A study of Homo sapiens with 2 samples.

How the data were processed

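MCF7 is an estrogen receptor-positive human breast cancer cell line. Dimethylation of lysine 4 of histone H3 (H3K4me2), a mark of promoters and of other active regulatory elements, was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq). There was 1 untreated library and 1 library from cells treated with estradiol (E2, the main natural estrogen) at 1e-08 M for 45 min. Both used the same antibody lot, and cells were grown in medium with fetal bovine serum, per the labels' protocols. The labels do not say whether hormones were removed from the serum before treatment.

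The authors deposited 1 peak list per library, with 5 columns: chromosome, start, end, peak name and a score for each peak. The peak names carry the name of the peak caller MACS, so peaks were called separately for each library. The build is hg19, per the names of the deposited files. The MACS version, its settings, any control library, the aligner and the handling of repeated or multiply matching reads are not given in the sources used here. The score in the deposited lists is the authors' own value for each peak, and its scale is not named. It was 50 or above in both lists, and it was used here to describe, rank or filter peaks within a list. Scores of the 2 lists are set beside each other only to match regions and to give a rank correlation across matched peaks, not to measure a change. The peaks in each list were numbered from 1 without a break, so neither list had numbered peaks missing. The lists hold no read counts. The depth of each library is therefore unknown, and no value here carries a read-based error.

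Starts are printed counted from 1, as a genome browser shows them. Peaks were compared by overlap with bedtools 2.31.1, and a peak was called shared when at least 1 bp overlapped a peak of the other list. The remaining peaks are called untreated-only or E2-only, which means that no overlapping peak was called in the other library. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. The overlap step was tested on simulated data. A second list was made from 20000 slightly moved copies of untreated peaks and 10000 intervals placed away from the 41269 untreated peaks. All copies were found shared and all new intervals one-list, as their construction requires. Of the untreated peaks without a copy, 99.6% were called one-list. On the real lists, bedtools and an independent interval search gave the same calls.

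Chance overlap was taken from 100 random placements of the E2 peaks, each on its own chromosome between the first and the last peak called there. Shares of peaks are given with Wilson 95% intervals, and ratios of peak numbers with exact (Clopper-Pearson) 95% intervals. These intervals cover counting error only and treat peaks as independent, which neighbouring peaks are not. With 1 library per condition there is no replicate spread, so no test between conditions was made. A difference between the lists compares these libraries, not the conditions.

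The regions named in the text were chosen by a rule written before the data were examined. It takes the 10 untreated-only and the 10 E2-only peaks with the highest score of their list, and the 5 highest-scoring peaks of each list. Windows of 5 Mb, the widest peaks, runs of one-list peaks, peak-free stretches, distances to shared peaks and the comparison of chromosomes X and Y were added after the data were seen. Shares of peaks at promoters, gene lists, peaks near estrogen-induced genes and sequence motifs had also been planned. They need a gene annotation and a genome sequence of hg19, which were not used here, so regions are given by position only and no gene is assigned to them. The alternatives tried were other overlap minimums, stricter score limits, lists of equal length, merging of close peaks, a fixed peak width, another random placement, other limits on distance and on the number of highest-scoring peaks, and the omission of chromosomes or of doubtful peaks.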

Results

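The data comprised H3K4me2 peaks from 1 untreated MCF7 library and 1 library taken 45 min after E2 was added. The series as a whole is about the forkhead factor FOXA1, a protein that opens chromatin for the estrogen receptor. The comparison asked where the H3K4me2 map of MCF7 cells differed after a short estrogen exposure. The untreated list held 41269 peaks that covered 24.3 Mb, and the E2 list held 47890 peaks that covered 35.7 Mb. The E2 list was thus 1.16 times as long and covered 1.47 times as much sequence. The median peak width was 505 bp in the untreated list (quartiles 349 and 733 bp) and 635 bp in the E2 list (quartiles 471 and 940 bp). The narrowest peak measured 119 bp in the untreated list and 202 bp in the E2 list.

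Counted by any overlap, the larger part of the untreated H3K4me2 peaks was also called after E2, which did not hold when 50% of both peaks had to overlap. Of the untreated peaks, 30039 overlapped an E2 peak, which was 72.8% of the list (Wilson 95% interval 72.4 to 73.2%). Of the E2 peaks, 28183 overlapped an untreated peak, or 58.8% (58.4 to 59.3%). The remaining 11230 untreated-only peaks made up 27.2% of their list (26.8 to 27.6%), and the 19707 E2-only peaks made up 41.2% of theirs (40.7 to 41.6%). With an overlap of at least 50% of both peaks, the one-list shares were 52.7% and 59.2%. Random placement of the E2 peaks overlapped 935 ± 26.0 untreated peaks (SD over 100 placements), so the observed overlap was 32.1-fold above this chance level. It was 20.9-fold above chance when each E2 peak was instead moved by 10 to 100 kb from its own place. None of the 100 placements of either kind reached it.

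The difference between the 2 one-list shares was 13.9 percentage points. It narrowed to 2.44 points when 20634 top-scoring peaks of each list were set against the 41269 top-scoring peaks of the other. The E2-only share was then 21.2% and the untreated-only share 18.8%. No replicate spread exists against which the remaining difference could be set.

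Peaks found in a single list had lower median scores and widths than the shared peaks of that list. Some of the highest-scoring E2 peaks were nevertheless E2-only, whereas the highest untreated-only score was 300.3 in a list that reached 3100. In the untreated list, the median score was 90.9 for shared peaks and 66.3 for untreated-only peaks, and the median width was 554 and 385 bp. In the E2 list, the median score was 105.7 for shared peaks and 72.9 for E2-only peaks, and the median width was 795 and 515 bp. In the highest-scoring 10% of the untreated list, 97.8% of peaks were shared (97.3 to 98.2%), against 54.4% in the lowest-scoring 10%. In the E2 list, 93.2% of the highest-scoring 10% was shared (92.4 to 93.9%), against 36.4% of the lowest-scoring 10%. In 25275 cases a single untreated peak matched a single E2 peak. Across these peaks, which are not independent replicates, the scores of the 2 libraries had a Spearman correlation of 0.40, and the E2 peak was the wider in 74.0% of them.

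**Figure D1:**
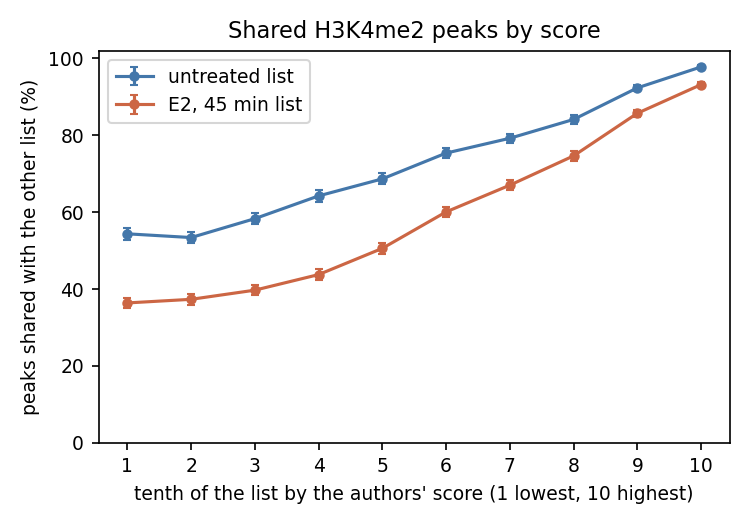
Share of peaks that overlap a peak of the other list (vertical axis, percent) in 10 score classes of equal size, by the authors' score within a list (horizontal axis), for the untreated and the E2 list. Bars are Wilson 95% intervals, which cover counting error only; the share lies at 97.8% in the highest class of the untreated list and at 93.2% in that of the E2 list.

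Just under 50% of the 200 highest-scoring H3K4me2 peaks of each library lay in the same 5 windows of the genome. Windows of 5 Mb that held at least 10 of the 200 highest-scoring peaks in both lists were found on chromosome 17 (55 to 60 Mb), chromosome 20 (45 to 50 Mb and 50 to 55 Mb), chromosome 3 (60 to 65 Mb) and chromosome 1 (145 to 150 Mb). MCF7 cells are known for high-level gains of DNA on chromosomes 1, 3, 17 and 20. Copy number was not measured here, so a match by chromosome does not place these windows inside gained DNA. The chromosome 17 window held 25 of the 200 highest-scoring untreated peaks and 27 of the 200 highest-scoring E2 peaks. The chromosome 20 window from 50 Mb held 23 in each list, and the one from 45 Mb held 20 in the untreated and 16 in the E2 list. The chromosome 3 window held 12 and 10, and the chromosome 1 window held 11 and 12, respectively. Together these 5 windows held 45.5% of the 200 highest-scoring untreated peaks (38.7 to 52.4%) and 44.0% of those of the E2 list (37.3 to 50.9%). They held 2.07% of all peaks in either list. The share depended on the number of peaks taken, being 65.0% and 58.0% of the 100 highest-scoring peaks and 28.0% and 29.4% of the 500 highest-scoring. Among 10000 random draws of 200 peaks, the fullest window of any draw held 7 peaks in the untreated list and 8 in the E2 list.

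**Figure D2:**
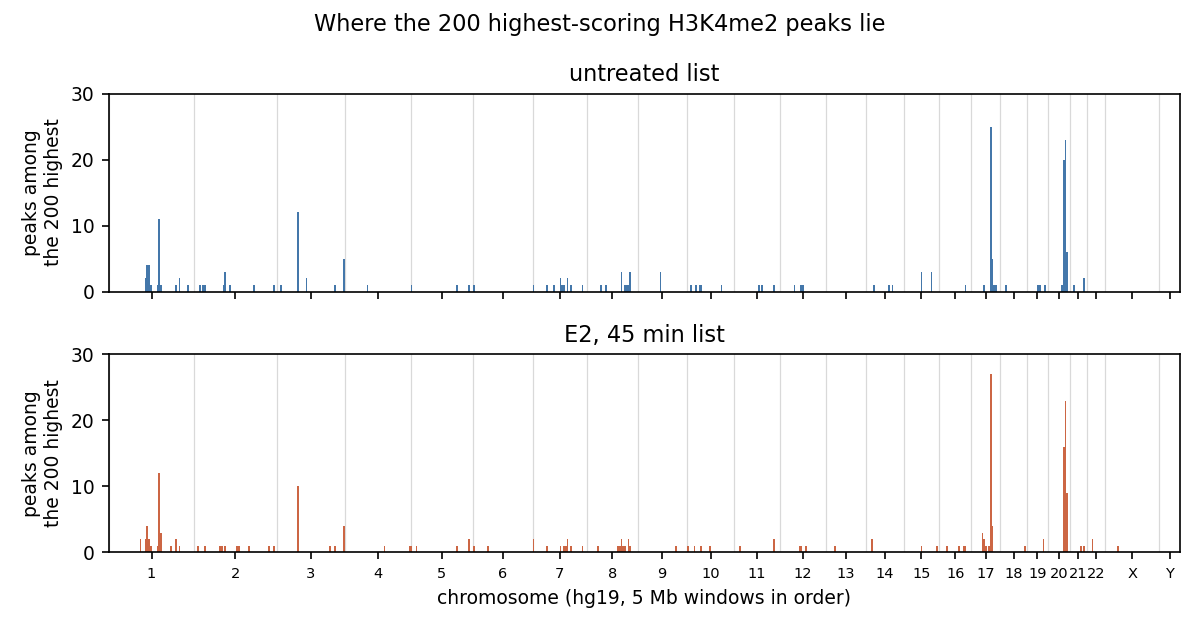
Number of peaks among the 200 highest-scoring of a list (vertical axis) in each 5 Mb window along hg19 (horizontal axis, chromosomes in order), for the untreated list above and the E2 list below. The tallest bars stand on chromosome 17, with 25 and 27 peaks, and on chromosome 20, with 23 in each list.

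A smaller share of the peaks in these windows was found in a single list. Untreated-only peaks made up 13.8% of the untreated peaks inside the 5 windows and 27.5% outside, and E2-only peaks made up 30.6% of the E2 peaks inside and 41.4% outside. The exception was the chromosome 3 window in the E2 list, where 45.0% of 151 peaks were E2-only.

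Among the 5 highest-scoring untreated peaks, all of which had an E2 peak over them, were chromosome 17: 59938444 to 59942375 (score 1056) and chromosome 20: 52307628 to 52309034 (score 1003). The E2 peaks at these places had scores of 1170 and 646.7. A 320 bp peak at chromosome 3: 196625533 to 196625852 scored 1161 in the untreated list, and its E2 counterpart scored 417.4. The highest untreated score, 3100, belonged to chromosome 1: 121483733 to 121485512, and the next, 1499, to chromosome 10: 42596619 to 42600774. Both of these lay within 1 Mb of a stretch of over 2.5 Mb in which neither list had a peak. In the E2 list the highest scores were 2116 at chromosome 2: 33141136 to 33141785 and 1899 at chromosome X: 36602271 to 36602710. The overlapping untreated peaks scored 135.0 and 180.5. The next E2 peaks by score were chromosome 6: 861773 to 864010 (score 1769, untreated 949.2) and chromosome 20: 52531110 to 52533099 (score 1491, untreated 817.3). The fifth was the chromosome 1 region that led the untreated list, with a score of 1458. Scores of different lists are set side by side here to locate the regions and do not measure a change.

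Of the 10 highest-scoring untreated-only peaks, the first and the third lay next to each other on chromosome 17. The untreated-only peak with the highest score, 300.3, spanned 6078 bp at chromosome 17: 57913780 to 57919857, and the third, with a score of 272.5, spanned 3953 bp at 57922143 to 57926095. A pair of further untreated-only peaks followed at 57930375 to 57931568 (score 111.9) and 57933993 to 57935269 (score 146.4). These 4 peaks summed to 12502 bp within 21.5 kb, inside the chromosome 17 window that held the most high-scoring peaks in both lists. The E2 list had no peak between 57907515 and 57936338, a gap of 28.8 kb, while peaks on both sides were called in both libraries. At 57936339 to 57938428 the E2 peak scored 311.0 and its untreated counterpart 303.9. The next shared peaks outward scored 253.4 in the E2 and 284.5 in the untreated list on the right, and 63.6 and 140.3 on the left. No other run of 3 or more untreated-only peaks in either list reached a score as high, the next being 171.6 at chromosome 10: 99159577 to 99185541. The highest for a run of E2-only peaks was 248.6 at chromosome 14: 68323223 to 68335633.

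**Figure D3:**
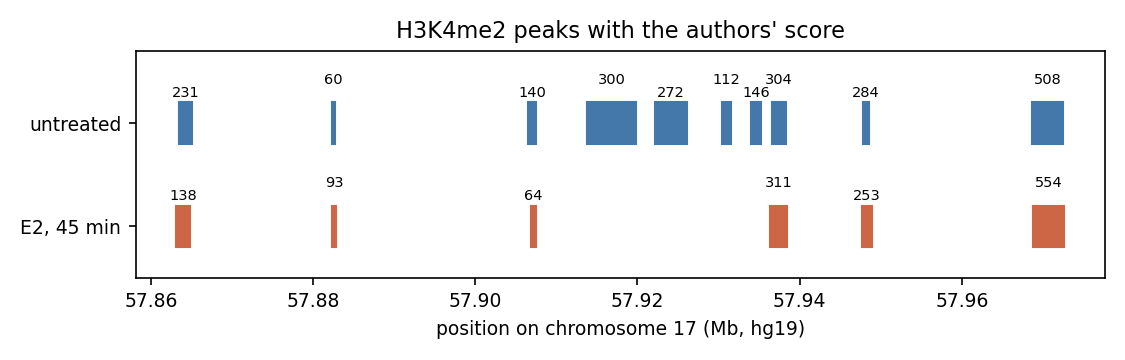
H3K4me2 peaks of the untreated list (upper row) and the E2 list (lower row) along chromosome 17 (horizontal axis, Mb on hg19), drawn to scale, with the authors' score above each peak. The 4 untreated-only peaks, with scores between 111.9 and 300.3, lie over the 28.8 kb stretch where the E2 list has no peak.

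The other 8 of the 10 highest-scoring untreated-only peaks lay apart from each other. They were chromosome 15: 79867160 to 79867650 (score 298.8), chromosome 21: 34755320 to 34756296 (244.4), chromosome 14: 68140144 to 68140914 (220.8), chromosome 9: 42818962 to 42819227 (216.1), chromosome 8: 103818031 to 103818684 (214.8), chromosome 17: 45234201 to 45234496 (214.6), chromosome 3: 11313365 to 11313893 (212.8) and chromosome 2: 101857079 to 101857253 (209.5).

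The 10 highest-scoring E2-only peaks were narrow beside the shared E2 peaks of high score. The 10 with the highest score measured 386 to 647 bp, with a median of 420.5 bp, and scored 571.8 to 1091. They lay at chromosome 10: 68716977 to 68717393 (score 1091), chromosome 10: 4073256 to 4073683 (984.6), chromosome 3: 159546006 to 159546652 (910.3), chromosome 16: 78355011 to 78355478 (832.8), chromosome 8: 34327204 to 34327608 (780.1), chromosome 16: 58781324 to 58781730 (733.8), chromosome 1: 91505640 to 91506063 (713.0), chromosome 7: 147044349 to 147044757 (668.2), chromosome 11: 18489322 to 18489746 (606.8) and chromosome 18: 70195960 to 70196345 (571.8). None of them lay in the 5 windows with the most high-scoring peaks. Among E2 peaks with a score of 300 or more, 28 of 434 were E2-only, with a median width of 424 bp, against 1354.5 bp for the 406 shared ones. The contrast in width depended on this score limit: at a score of 200 or more, 144 of 2752 peaks were E2-only, with a median width of 888.5 bp against 1122 bp for shared ones. In the untreated list 1 of 325 peaks with a score of 300 or more was untreated-only, the 6078 bp region on chromosome 17. At a score of 200 or more, 15 of 1781 were untreated-only.

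Pairs of H3K4me2 peaks separated by a short gap made up a larger share of the untreated list. Adjacent peaks on either side of a short gap can be the flanks of an element whose centre lacks a nucleosome. In the untreated list 3795 of 41244 neighbouring pairs, or 9.20% (8.93 to 9.48%), were less than 500 bp apart, and in the E2 list 2845 of 47866, or 5.94% (5.74 to 6.16%). In the upper 50% of each list by score, the shares were 4.27% and 1.77%. An E2 peak covered 2 or more untreated peaks in 2220 cases, and an untreated peak covered 2 or more E2 peaks in 402. The E2 peaks were also wider, as given above, and the share of close pairs was not compared at equal peak width.

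Each of chromosomes 1 to 22 and X carried more E2 than untreated peaks, the E2 list being 1.16 times as long. The ratio was lowest on chromosome 19, at 1.04 (exact 95% interval 0.97 to 1.12), and on chromosome 17, at 1.06 (0.99 to 1.12). It was highest on chromosome X, at 1.29 (1.199 to 1.381), on chromosome 18, at 1.25 (1.11 to 1.39), and on chromosome 4, at 1.23 (1.16 to 1.32). With 20634 top-scoring peaks from each list, the E2 list no longer led on every chromosome. The ratio was then 0.85 on chromosome 19, 0.88 on chromosome 17 and 1.31 on chromosome X. Among chromosomes 1 to 22 and X, shared peaks were densest on chromosome 19, with 18.1 per Mb in the untreated list, and sparsest on chromosome 18, with 5.02 per Mb, which is a 3.60-fold range. On the same chromosomes untreated-only peaks ranged 3.62-fold, from 2.23 to 8.08 per Mb, and E2-only peaks 2.42-fold, from 4.30 to 10.4 per Mb, each again from chromosome 18 to chromosome 19.

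**Figure D4:**
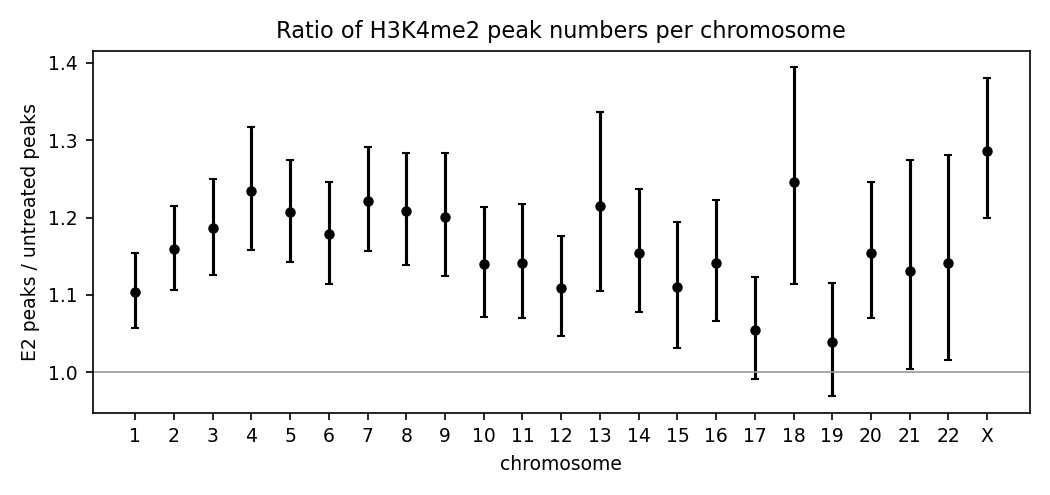
Number of E2 peaks divided by the number of untreated peaks (vertical axis, no unit) on each chromosome (horizontal axis). Points are ratios and bars are exact 95% intervals for counting error; the values run from 1.04 on chromosome 19 to 1.29 on chromosome X, and the line marks equal numbers.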

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

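No paired analysis was possible because each condition holds 1 library, and no library could be left out for the same reason. The E2-only share exceeded the untreated-only share under all 12 alternatives, by 2.17 to 14.9 percentage points. This agreement is no separate evidence, because overlap is mutual and the longer list is left with more peaks without a partner. With 50% of both peaks, 19518 peaks were shared in each list, so those 2 shares differ only through list length. The values below are given for the untreated list first and the E2 list second. The one-list shares were 52.7% and 59.2% when the overlap had to reach 50% of both peaks, with 21751 untreated-only peaks, and 29.9% and 43.1% with 50% of the shorter peak. They were 23.1% and 37.9% when peaks within 500 bp counted as shared, and 29.9% and 42.2% with every peak set to 500 bp. The upper 50% of each list by score gave 35.9% and 46.7% (7416 and 11173 peaks), and 14.2% and 23.9% (2935 and 5715 peaks) against all peaks of the other list. Equal numbers of top-scoring peaks gave 41.3% and 43.4%, with 8960 E2-only peaks, and equally long other lists, an alternative chosen after seeing the data, gave 18.8% and 21.2%. Without chromosomes 1, 17 and 20 the E2-only share was 41.8%. Merging of close peaks, and the omission, chosen after seeing the data, of chromosomes Y and M with peaks near long peak-free stretches or of narrow high-score peaks, left both shares inside their intervals. The further alternatives on scores, chance and windows were also chosen after seeing the data. With 50% of both peaks, the median scores were 103.0 (shared) and 69.5 (one-list) in the untreated list and 78.6 (one-list) in the E2 list, and with 500 bp the shared medians were 89.2 and 103.1. Moving each E2 peak by 10 to 100 kb gave a 20.9-fold excess of overlap. Neighbours within 1 kb made up 14.9% and 9.11%, and those within 500 bp in the upper 50% by score 4.27% and 1.77%. With equal numbers of top-scoring peaks, 19 of 24 chromosome ratios left their intervals, and that of chromosome 19 was 0.85. Lists of equal length lower these ratios as a group, so the count mostly restates the difference in list length. The 5 windows held 65.0% and 58.0% of the 100 and 28.0% and 29.4% of the 500 highest-scoring peaks. The cause of these differences was not tested. The analyses of promoters, gene lists, estrogen-induced genes and motifs were not run. Read depth, which decides how many weak regions a peak caller accepts, is unknown for both libraries.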

Other observations

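Several of the widest called peaks lay beside long stretches without peaks, and whether they reflect H3K4me2 at these places was not tested. Of the 5 widest untreated peaks, 3 lay within 1 Mb of a stretch of over 2.5 Mb without peaks, at chromosome 7: 61967085 to 61973882 (6798 bp), chromosome 6: 58773543 to 58780244 (6702 bp) and chromosome 18: 18514578 to 18520420 (5843 bp). Of the 5 widest E2 peaks, 1 was such a region, on chromosome 7, and 3 lay on chromosome 1, at 149829405 to 149835899 (6495 bp), 149801047 to 149806880 (5834 bp) and 151960480 to 151966144 (5665 bp). In the untreated list the first 2 of these 3 regions were each called as 2 peaks. Peaks of 3 kb or more numbered 56 in the untreated list, of which 13 were untreated-only, and 123 in the E2 list, of which 7 were E2-only.

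Regions beside the 21 long peak-free stretches held 644 untreated and 745 E2 peaks, and 37.6% and 49.0% of these were found in 1 list only. On chromosomes X and Y, 22 pairs of untreated peaks and 33 pairs of E2 peaks lay at an offset of 50 kb (counted to the nearest kb), and no other offset had more than 12 pairs in either list. The handling of multiply matching reads is not given, so the lists do not show whether peaks on chromosome Y arose there. In 5 Mb windows with at least 30 peaks in both lists, the median ratio of E2 to untreated peaks was 1.17. It ranged from 0.55 on chromosome Y (10 to 15 Mb, exact 95% interval 0.34 to 0.87) to 1.85 on chromosome 14 (25 to 30 Mb, 1.202 to 2.901). The lowest ratio outside chromosome Y was 0.77 on chromosome 1 (170 to 175 Mb, 0.56 to 1.06). These windows are extremes picked from 526, and their intervals are not adjusted for that choice, so they do not show that a window differs.

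The tests that follow were chosen after the patterns were seen. Those of distance to shared or neighbouring peaks, and that of the windows without their highest-scoring peaks, had their outcomes set out before the values were known; the other tests were set out after them.

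The E2 list held the larger share of one-list peaks, by 13.9 percentage points. By counting alone, the excess of 19707 E2-only over 11230 untreated-only peaks has 2 parts. The first is the 6621 more peaks in the E2 list. The second is the number of shared peaks, 30039 untreated against 28183 E2. It arises because 2220 E2 peaks covered 2 or more untreated peaks, against 402 cases the other way. A candidate explanation for the difference in shares is the greater length, with more calls close to the score limit. The difference in shares was 9.64 points for the upper 50% of each list by score against all peaks of the other. With the other list also held to an equal length it was 2.44 points, between the 2 points set as the limit for this explanation alone and the 5 points set against it. Random background calls stay open as a part of the excess: E2-only peaks lay within 10 kb of a shared peak in 23.2% of cases, 1.35 times the 17.2% of randomly placed intervals, against 2.05 times for untreated-only peaks, and the effect of peak width on this was not tested. A response to estradiol remains untested, since there is 1 library per group and treatment and library cannot be told apart.

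Of the 28 E2-only peaks with a score of 300 or more, 22 were 500 bp wide or less, against 8 of the 406 shared ones. At a score of 200 or more the median width of E2-only peaks was 888.5 bp, above the 10th percentile of the shared peaks (694.7 bp), so the narrowness rests on the highest scores. Within 10 kb of another E2 peak lay 14.3% of the 28 (Wilson 95% interval 5.70 to 31.5%), against 47.3% of the shared ones (42.5 to 52.1%). By the outcome set out beforehand, this goes against elements of the same kind as the shared peaks. At a score of 200 or more the shares were 13.2% of 144 E2-only peaks and 33.1% of shared ones, so the gap is not particular to narrow peaks. The local density of peaks was not matched, so the gap alone does not decide the question. Whether reads stacked at one spot in the E2 library may account for them stays open: their median width of 424 bp is the feature that drew attention to them, so it decides nothing. A short element that gained the mark after E2 stays open too, because the reads behind these peaks were not used here.

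The highest scores gathered in 5 windows on chromosomes 1, 3, 17 and 20. Taken from the E2 list alone, all 5 windows with 10 or more of its 200 highest-scoring peaks also held 10 or more in the untreated list. The gathering was thus present in the library without added E2. The windows had already been found as those high in both lists, so this restates the pattern and is not a separate test. With the 200 highest-scoring peaks removed, the median score of the remaining peaks of these windows was 107.8 in the untreated and 101.0 in the E2 list. This was at or above the 99.95 percentile of 10000 random sets of 5 other windows in both. It met the outcome set out beforehand for more DNA copies of the whole window. However, the windows had been chosen for high scores in these same lists, which by itself raises the median, so the result does not decide for more copies. The raised median held unevenly window by window, ranked by median score of all peaks among windows with at least 30 peaks in a list. Ranks ran to 527 in the untreated and 568 in the E2 list. The chromosome 3 window ranked 2nd in the untreated and 69th in the E2 list, and the chromosome 17 window 4th and 18th. The chromosome 20 windows ranked 1st and 5th (from 50 Mb) and 3rd and 6th (from 45 Mb). The chromosome 1 window ranked 16th and 4th. A greater local density of strong regulatory elements would give the same result and was not tested, as no control library was used here.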
